A study of Mus musculus with 15 samples.

How the data were processed

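DNase-seq was done on bone marrow derived macrophages of C57BL/6J mice that were wild type, littermate controls or Ikzf KO, after 0, 3 or 8 h with 10 ng/ml LPS, with 15 libraries in all. Groups are genotype and hours of LPS as the sample labels give them, with 2 WT, 1 littermate and 2 KO libraries per time. The titles of WT replicate 1 and of all littermate and KO libraries give 80 U of DNase and those of WT replicate 2 give 100 U, whereas the protocol text names one amount for all, so the DNase amount coincides with the replicate number in WT. Per the labels' protocols, nuclei were digested with DNase I, fragments were selected by size on a sucrose gradient, and libraries were sequenced as single ends.

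The authors deposited one hotspot list per library. Per the submitters' processing notes, the build is mm9 and CASAVA was used; the aligner, the hotspot caller and its threshold are not given in the sources used here. Per the file headers, each hotspot has its chromosome, start and end, a highest and a mean tag density, a Z-score and a p-value. The deposited tag density is a signal, the Z-score is a score and the p-value follows from the Z-score as its two-sided normal tail in every list. The authors called each library separately. The littermate and KO lists reach down to Z-scores of 3.40 to 4.54 and the WT lists only to 7.98 to 10.6, so the lists were cut at different levels and their lengths are not comparable between WT and the rest. KO was therefore compared with littermate lists of the same kind. In the main comparisons WT lists were used with KO only after lists were made equally long. KO and littermate lists were not cut alike either. KO lists reached down to 3.40 to 3.66, each lower than the littermate list of its time (4.38 at 0 h, 4.54 at 3 h and 3.65 at 8 h). Scores were used only to rank or filter hotspots within a list and to describe the libraries.

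The lists hold no read counts, and depth is unknown. The highest tag densities of a list are whole multiples of one step (within 0.05 steps for at least 99.99% of hotspots in each list), and the step ran from 0.237 to 0.451. If the authors scaled each library to the same total, which the sources do not state, the inverse of the step gives relative depth, and the shallowest library had 0.525 times the depth of the deepest. On that reading every KO library (0.741 to 1) was deeper than every littermate library (0.525, 0.630 and 0.712). At 8 h the control libraries lay at 0.683 to 0.712 and the KO libraries at 0.85 and 1. Depth can therefore not be told apart from genotype in these comparisons. No interval for sequencing depth can be given. Hotspots on chromosomes 1 to 19, X and Y were used, with coordinates as the lists give them; whether they count from 0 or 1 is not stated.

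From the lists, hotspots per library, covered length and Jaccard indices were computed. For gained and lost regions, each list of a comparison was shortened to the length of the shortest by Z-score, hotspots sharing at least 1 bp were merged over the lists into union regions, and a region was present in a list if at least 1 bp was covered. LPS-gained regions were in every list of the later time and in none at 0 h, KO-gained regions in all KO and in no littermate list, and lost regions the reverse. A region gained in this sense entered the strongest hotspots of each list and can be in a deposited list at a lower rank. Shares have Wilson 95% intervals. Differences in list size and similarity were tested by exact two-sided permutation of times within genotype or of the littermate label within each time, with Benjamini-Hochberg adjustment over 9 tests of list size, covered length and Z-score at equal rank and over 4 tests of similarity. Counts of regions were set beside the counts under other splits of the libraries within genotype or time. A split of times and its reversal were counted once, giving 36 splits.

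The region counts were tested on simulated lists for KO against littermate, with 58390 regions of which 200 were planted as KO-gained and 200 as KO-lost. All were recovered when no hotspot was missed. When each list missed 2% of its hotspots at random (rate 0.02), 89.0% of gained and 93.0% of lost regions were recovered with 0 false calls. At a rate of 0.1, 55.0% and 72.0% were recovered, with 29 false gained and 0 false lost calls. Missed hotspots thus lowered the recovery of planted regions but added false calls on the gained side. Absence from 3 lists arises by chance more often than absence from 6. All simulated lists missed hotspots at one rate and were not shortened by Z-score. The simulation does not cover littermate lists that miss more hotspots than KO lists, where the KO-gained count may be too high.

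The annotation at hand is of another build (GRCm38.p6), and no mm9 genome or annotation was used here. Gene assignment, promoter shares, motif shares, the gene lists and cell type markers fixed in the design (inflammatory cytokines, NF-kB pathway, interferon response, macrophage identity, Ikaros family, Notch pathway, stem and progenitor, housekeeping, and markers of other blood cell types and fibroblasts) were therefore not analysed, and neither was the targeted locus. The rule for named items was then to give positions only: for LPS-gained regions at 8 h and 3 h, LPS-lost regions at 8 h, KO-gained and KO-lost regions, the 5 regions with the highest mean rank by Z-score over the lists that hold them.

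Groups, tests of the planned comparisons, the naming rule and most alternatives were chosen before the data were examined; the bounds used to judge explanations were not. Alternatives were the lists as deposited, lists of 0.5 times the equal length, 50% of a union region covered, fixed bins of 500 bp, each series left out, other control sets, a Fisher exact test per region, the replicate number as a block, covered length, and 80 U libraries alone. Added after the data were seen were ranking by the highest tag density, a common Z-score minimum, the comparison of KO with all controls at 8 h, regions defined in 2 control series and looked up in the remaining one, regions defined at 0 h and 3 h and looked up at 8 h, and absence from all deposited lists of the other side. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.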

Results

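The study followed chromatin accessibility in bone marrow derived macrophages of C57BL/6J mice during the response to lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that activates macrophages through Toll-like receptor 4. DNase-seq reads out accessible chromatin as stretches of the genome that DNase I digests readily, and the authors listed these stretches as hotspots for each library. The series title names Ikaros, a zinc finger protein of lymphoid and myeloid cells encoded by Ikzf1, and the labels call the mutant genotype Ikzf KO. Cells received 10 ng/ml LPS for 0, 3 or 8 h. Each time had 2 wild-type (WT) libraries, 1 littermate control library and 2 KO libraries, 15 libraries in 9 groups. WT and littermate libraries together are called controls here, and the libraries of one genotype that carry the same replicate number at the 3 times are called a series. Nothing in the labels says whether replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

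Hotspot lists grew after 8 h of LPS in every series, and KO lists were long already before LPS. At 0 h the lists held 19307 ± 2927 hotspots in WT (SD, n = 2), 64262 in the littermate library and 112190 ± 900 in KO (SD, n = 2). At 8 h they held 49959 ± 2652 in WT, 114427 in the littermate and 128765 ± 4970 in KO. Averaged over the 5 series, 8 h lists were longer than 0 h lists by 28924 hotspots (exact permutation of times within genotype, two-sided p = 0.0031, adjusted p = 0.0094 over 9 tests). They covered 30.8 Mb more (exact permutation p = 0.0012, adjusted p = 0.0056). All 5 series gained hotspots, by a factor of 2.79 and 2.42 in the WT series, 1.78 in the littermate series and 1.12 and 1.17 in the KO series. In each series the 8 h list also reached down to a lower Z-score than the 0 h list. This lowest Z-score went from 8.29 to 7.98 and from 9.29 to 8.35 in WT. It went from 4.38 to 3.65 in the littermate, and from 3.64 to 3.47 and from 3.66 to 3.40 in KO. Relative depth, if the density steps give it, was also higher at 8 h in each series. The shares of LPS, cut and depth in this growth cannot be told apart. At 3 h the mean difference from 0 h was -345.4 hotspots (exact permutation p = 0.98). That permutation moves the 8 h labels too, so its spread includes the longer 8 h lists. It therefore says little on 3 h against 0 h alone. KO lists held 42854 more hotspots than littermate lists of the same times, and 6 of 6 KO lists were longer than the littermate list of their time. That difference had an exact two-sided permutation p of 0.037, the smallest that 27 arrangements allow, and an adjusted p of 0.056, which did not pass 0.05. The arrangements relabel the littermate library at each time separately, although the littermate libraries form a single series. Relative depth, if the density steps give it, was also lower in every littermate library (0.525 to 0.712) than in every KO library (0.741 to 1). Each KO list also reached down to a lower Z-score than the littermate list of its time, so the excess did not come from equally cut lists.

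**Figure D1:**
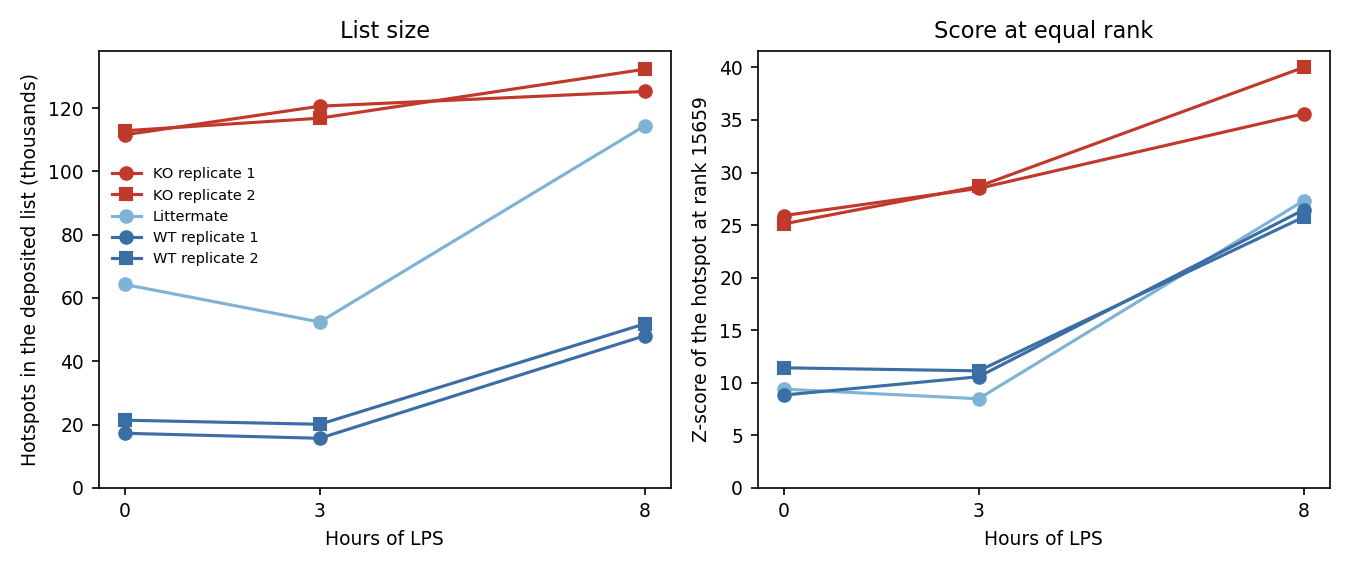
Left, number of hotspots in each deposited list (axis in units of 1000) against hours of LPS; right, the authors' Z-score of the hotspot at rank 15659, the length of the shortest list. Each point is 1 library and lines join the libraries of a series, with circles for replicate 1 (and the single littermate series) and squares for replicate 2. On the right the 6 control libraries at 0 h and 3 h lie between 8.48 and 11.4, and the other 9 libraries between 25.1 and 40.01.

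Control libraries at 0 h and 3 h stood apart from the rest in the strength of their best hotspots. At rank 15659 the Z-score was 8.48 to 11.4 in these 6 libraries, 25.8 to 27.3 in the 3 control libraries at 8 h and 25.1 to 40.01 in KO. The mean tag density over the 15659 best hotspots was 3.92 to 5.85 in the 6 libraries and 9.32 to 13.3 in the other 9, and those hotspots covered 10.4 to 15.3 Mb against 20.7 to 32.6 Mb. This split runs along time in the controls and along genotype at 0 h and 3 h, so it stands beside each comparison of controls with KO at those times and beside each comparison of 8 h with earlier times in controls. The comparisons within KO, between WT at 0 h and 3 h, and between genotypes at 8 h do not cross it.

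A small set of regions entered or left the strongest hotspots of all genotypes with LPS. To compare lists of different length, each list was shortened to its highest Z-scores until all lists of a comparison were equally long. A region counted as gained if it was in every shortened list of the later time and in none at 0 h, and as lost in the reverse case. With 17237 hotspots per list, 510 regions were gained and 204 lost at 8 h in all 5 series, while 8833 regions were in all 10 lists. At 3 h, with 15659 hotspots per list, 245 were gained and 187 lost, and 7366 were in all 10 lists. Gained regions at 8 h had a median length of 1790 bp, lost regions 1493 bp, and regions in all 10 lists 2281 bp. Union regions span the hotspots of every list that holds them, so those in all 10 lists are longer partly by construction. In the lists as deposited the counts were 1211 gained and 1 lost at 8 h, and 30 gained and 3 lost at 3 h, so the balance of gained and lost rests on the list length at both times. Without WT replicate 1 the equal lists were longer, with 21377 hotspots at 8 h and 20077 at 3 h. The counts were then 795 gained and 370 lost at 8 h, and 429 and 382 at 3 h.

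The strongest LPS-gained regions are given by position in the mouse build mm9, with coordinates as in the deposited lists. At 8 h they were chromosome 5 from 105720828 to 105723885 (mean rank 2218 of 17237), chromosome 11 from 116238019 to 116239395 (mean rank 2333), chromosome 5 from 29615378 to 29617647 (mean rank 2552), chromosome 10 from 57991752 to 57993225 (mean rank 3154) and chromosome 9 from 67271207 to 67272855 (mean rank 3803). Their Z-scores in the 8 h libraries lay between 63.0 and 123.4. The first of them was in 2 of the 5 deposited 0 h lists, both of them KO, and in all 5 lists at 3 h and at 8 h. The regions on chromosomes 11 and 10 were in 3 deposited 0 h lists each, and the other 2 were in 4, so these regions rose into the strongest hotspots from lower ranks or from below the authors' threshold. At 3 h the strongest gained regions were chromosome 2 from 173042810 to 173045895, chromosome 11 from 116237984 to 116239380, chromosome 5 from 105722029 to 105723753, chromosome 11 from 48899673 to 48902743 and chromosome 8 from 117943272 to 117945289. The strongest regions lost at 8 h were chromosome 5 from 64727385 to 64729327, chromosome 17 from 10563142 to 10565602, chromosome X from 166440137 to 166444326, chromosome 5 from 148173965 to 148175336 and chromosome 6 from 124323278 to 124326765. The chromosome 5 region at 64727385 was in all 5 deposited 0 h lists and in 3 lists at 8 h, and the chromosome X region stayed in all 5 lists at 8 h at lower ranks.

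Within WT, 2150 regions were gained and 1352 lost at 8 h, and 1377 were gained and 1226 lost at 3 h (15659 hotspots per list). Of the 23141 WT regions, 888 were in both 3 h and both 8 h lists and in neither 0 h list, 667 were in the 8 h lists alone and 294 in the 3 h lists alone. Another 739 were in the 0 h lists alone, and 9057 were in all 6 lists. In other divisions of the 0 h and 8 h libraries into pairs, 123 to 277 regions separated the pairs. With 2 against 2 libraries, the 6 possible splits cannot give a share below 0.167, so the counts are descriptive. In the lists as deposited the WT counts at 8 h were 21933 gained and 91 lost. At 3 h lost regions outnumbered gained ones as deposited (1132 gained and 1598 lost) and with 50% of a region covered (1114 and 1368), so the balance at 3 h is open. With 1 WT series alone the counts were 5187 and 4062 at 8 h and 4528 and 4817 at 3 h without replicate 1, and 4129 and 3499, and 3389 and 3567, without replicate 2. With 1 list per time, equal length by itself brings gained and lost counts close to each other, so single series say little on the balance.

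Within KO, more regions entered than left both replicates with LPS. Z-scores at rank 15659 also rose with time in KO. They were 25.9 and 25.1 at 0 h, 28.5 and 28.7 at 3 h, and 35.6 and 40.01 at 8 h. Relative depth, if the density steps give it, was 0.745 and 0.741 at 0 h and 0.85 and 1 at 8 h. The strength of the libraries was therefore not constant within KO. With 111553 hotspots per list, 10783 regions were gained and 3793 lost at 8 h, and 7844 were gained and 4329 lost at 3 h. Of 233685 KO regions, 4842 were in the 3 h and 8 h lists and not at 0 h, 3342 were in the 8 h lists alone, 1652 in the 3 h lists alone, 2411 in the 0 h lists alone and 59047 in all 6 lists. The regions gained at 3 h and kept at 8 h had a median length of 912 bp, against 624 bp for those at 8 h alone and 568 bp for those at 3 h alone. A union region spans the hotspots of every list that holds it, so these lengths also depend on the number of lists. Other divisions of the KO 0 h and 8 h libraries into pairs gave 1381 to 1795 regions. With 1 KO series alone, where the balance is again largely set by the equal length, 38826 regions were gained and 36295 lost without replicate 1, and 37003 and 35625 without replicate 2 at 8 h. At 3 h the single series gave 39423 and 39345, and 37402 and 36077. The KO lists are longer than the WT lists used above, so the counts of the genotypes are not compared with each other.

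Many more regions were in all KO lists and in no littermate list than the reverse. With 52400 hotspots per list, 3185 of 101275 regions were in all 6 KO lists and in none of the 3 littermate lists (KO-gained), and 357 were in all 3 littermate lists and in no KO list (KO-lost). Another 21002 regions were in all 9 lists. The counts were 5876 and 135 in the lists as deposited, and 1202 and 355 with lists of 0.5 times the length. With 1 KO series left out, so that 3 KO libraries faced 3 littermate libraries, the counts were 4191 gained and 458 lost without replicate 1, and 4394 gained and 479 lost without replicate 2. The WT libraries, which did not enter this definition, differed between the classes: 4.71% of the KO-gained regions were in both WT 8 h lists of 48084 hotspots (Wilson 95% interval 4.03 to 5.50, 150 of 3185), against 66.1% of the KO-lost regions (61.0 to 70.8, 236 of 357) and 97.8% of the regions in all 9 lists. The littermate 8 h list is part of the definition and resembled the WT 8 h lists, so these shares show how far the controls agreed at 8 h. Intervals here cover counting only, since neighbouring regions are not independent. With the WT libraries added to the controls and 15659 hotspots per list, 330 regions were KO-gained and 42 KO-lost.

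Of the KO-gained regions, 1055 (33.1%, Wilson 95% interval 31.5 to 34.8) were in none of the 9 control lists as deposited, and 61 of the KO-lost regions (17.1%, 13.5 to 21.3) were in none of the 6 KO lists. These 2 shares are not comparable, because the control lists held 15659 to 114427 hotspots and the KO lists 111553 to 132279. The WT lists also stopped at Z-scores of 7.98 to 10.6 and the KO lists at 3.40 to 3.66. The strongest KO-gained region, chromosome 18 from 43135305 to 43136009, had a mean rank of 1728 of 52400 in KO with Z-scores of 71.2 to 108.7, and was in no WT or littermate list. Chromosome 18 from 5818610 to 5821656 (mean rank 2265) and chromosome 8 from 37674826 to 37677716 (mean rank 2932) were each in 2 WT lists and 1 littermate list. Chromosome 15 from 77165993 to 77167875 (mean rank 3442) and chromosome 7 from 91404380 to 91406411 (mean rank 4205) were each in 1 littermate list and no WT list. The strongest KO-lost regions were chromosome 4 from 141549474 to 141550804, chromosome 8 from 92914521 to 92915987, chromosome 13 from 61905136 to 61906284, chromosome 13 from 101087134 to 101087827 and chromosome 7 from 46778800 to 46779907. The chromosome 13 region at 61905136 was in all 6 WT and all 3 littermate lists and in no KO list. The chromosome 7 region was in 5 WT lists, all 3 littermate lists and no KO list, whereas the chromosome 4 region was in 3 of the 6 KO lists as deposited.

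At single times, KO lists were set against 1 littermate list, with no replicate check. Equal list length then largely fixes that the 2 directions come out close, so the counts show the size of the difference and not its balance. At 0 h, 15983 regions were in both KO lists and not in the littermate list and 16031 the reverse; at 3 h the counts were 19054 and 18234, and at 8 h they were 9005 and 8856. In the lists as deposited the counts were 34833 and 20307 at 0 h, 45525 and 14519 at 3 h, and 19320 and 33943 at 8 h. At 8 h the Z-scores at rank 15659 were 25.8 to 27.3 in controls and 35.6 to 40.01 in KO, closer than at earlier times, and the 2 WT libraries were added there as controls, a comparison chosen after the data were seen. With 48084 hotspots per list, 6372 of 62541 regions were in both KO 8 h lists and in none of the 3 control lists, 3937 were the reverse, and 31242 were in all 5. No other way of naming 2 of the 5 libraries gave more than 1059 regions in the pair alone or more than 1417 in the other 3 alone. The 10 splits cannot give a share below 0.1. In the lists as deposited, where KO lists were the longest, the counts were 19678 and 621.

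At equal list length, regions that LPS added in controls were found less often in KO at 8 h than in a control library left out of the definition. With 17237 hotspots per list, 1522 regions were in all 3 control lists at 8 h and in none at 0 h. Of these, 55.3% were in both KO 8 h lists (Wilson 95% interval 52.7 to 57.7), 34.4% in neither (32.1 to 36.9), and 16.5% were in both KO 0 h lists (14.7 to 18.4). Both shares depended on the setting: over 8 settings they were 50.5% to 92.3% at 8 h and 16.5% to 72.4% at 0 h, highest in the lists as deposited. Of the 9770 regions in every control list, 93.0% were in both KO 8 h lists and 94.4% in both KO 0 h lists. Of the 864 regions lost in all 3 control series, 16.0% were in both KO 8 h lists and 42.5% in both KO 0 h lists. To set these shares against the spread between controls, gained regions were also defined in each pair of control series (2164 to 2219 regions). The control 8 h library left out held 82.4% to 88.5% of them and the KO 8 h libraries 57.0% to 59.3%, lower in all 6 comparisons. Regions in all 4 lists of a pair of control series were in 96.7% to 98.2% of cases in the control left out and in 92.3% to 92.9% in KO. The gap of 26.2 percentage points for gained regions depended on the list length and on how regions were formed: it was 16.7 points with lists of 0.5 times the length, 8.66 in bins of 500 bp, 6.72 with 50% of a region covered and 3.37 with a common Z-score minimum, and in the lists as deposited, where KO lists are longer than WT lists, KO libraries held more of the regions, by 10.2 points.

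**Figure D2:**
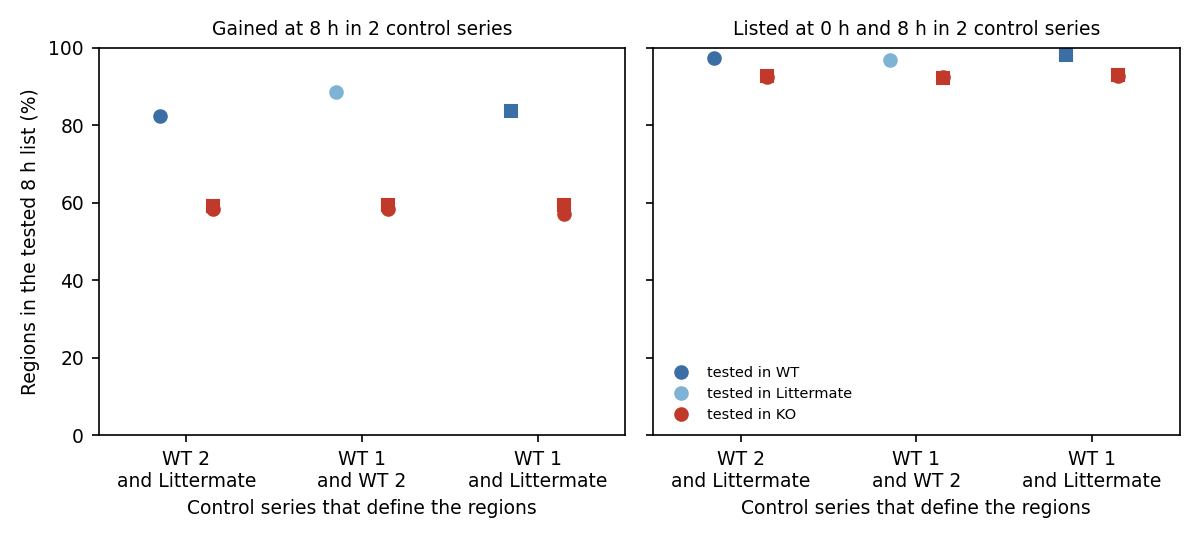
Percentage of regions found in the 8 h list of a library that did not define them, for regions gained at 8 h in 2 control series (left) and regions listed at 0 h and 8 h in those series (right), with 17237 hotspots per list. Each point is 1 library, red for KO and blue for the control left out, with circles for replicate 1 or the littermate and squares for replicate 2. For gained regions the control points lie between 82.4% and 88.5% and the KO points between 57.0% and 59.3%.

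Libraries resembled each other by genotype and by time. In the lists as deposited, the Jaccard index (base pairs shared by 2 lists over base pairs in either) was 0.591 to 0.757 between WT replicates and 0.629 to 0.666 between KO replicates. Within WT and KO, libraries of the same time exceeded libraries of different times by 0.174 (exact permutation of times within genotype, two-sided p = 0.0044, adjusted p = 0.0089 over 4 tests). This averages a difference of 0.283 in WT alone and 0.0643 in KO alone, each with an exact permutation p of 0.067. KO replicates of one time exceeded KO and littermate libraries of that time by 0.305 (exact permutation p = 0.037, the smallest that 27 arrangements allow, adjusted p = 0.037). These arrangements again treat the libraries of the single littermate series as separate. With 15659 hotspots in every list, KO and littermate libraries shared 0.382 at 0 h, 0.347 at 3 h and 0.586 at 8 h, and WT and littermate libraries 0.538, 0.556 and 0.637. KO libraries at 0 h resembled the littermate library at 8 h (0.534) more than the littermate library at 0 h (0.382), and KO and control 8 h libraries also shared the higher scores described above. The KO 3 h and 8 h libraries had an index of 0.712 and the KO 0 h and 8 h libraries 0.616, while WT 0 h libraries had 0.551 with WT 3 h libraries and 0.407 with WT 8 h libraries.

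**Figure D3:**
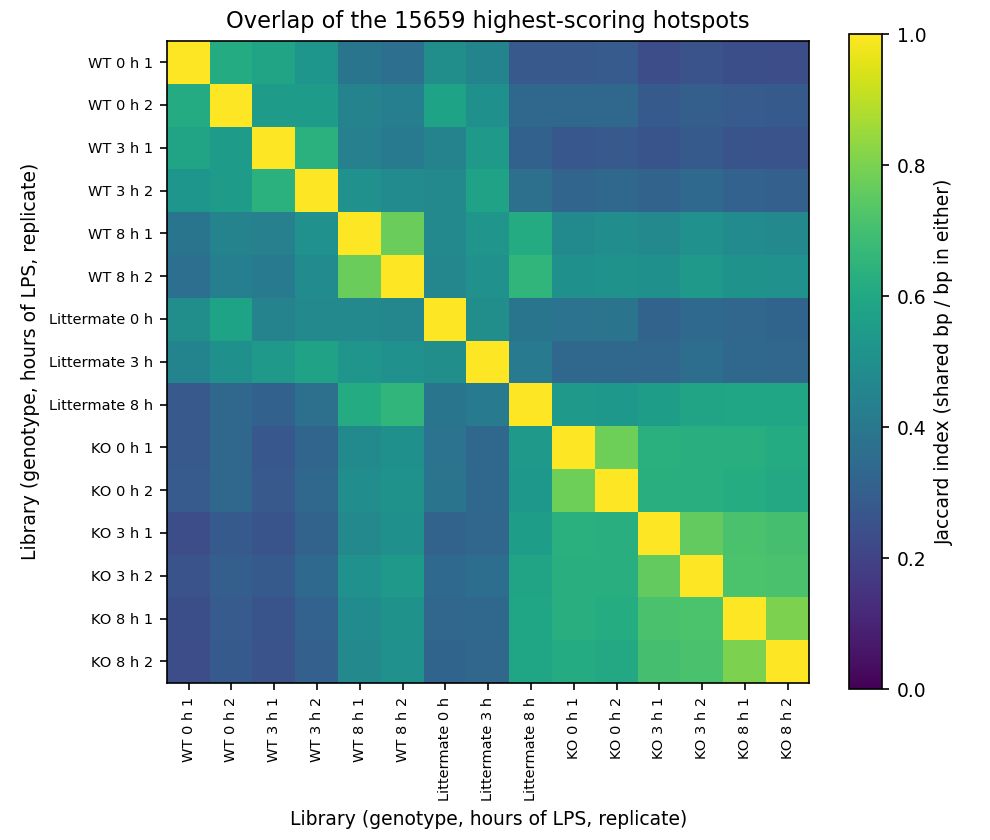
Jaccard index of each pair of libraries (colour scale from 0 to 1, base pairs shared over base pairs in either) with the 15659 highest-scoring hotspots of every list. Rows and columns are the 15 libraries, ordered by genotype, hours of LPS and replicate. KO libraries form a block in which replicates reach 0.759 to 0.801, and control libraries at 0 h and 3 h are least like KO.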

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

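The counts of splits were planned, but their bounds were written after the counts were seen, and all other tests of explanations in this part were chosen after the results were seen, except that the bounds for regions defined at 0 h and 3 h alone were written before that test was run. The bounds for depth, for KO cells at 0 h and for weak control libraries at 0 h were also revised after a first run of those tests: depth was first compared as a ratio of medians, with the same verdict, and the other 2 were made to hold in every setting, which left both open.

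Between 0 h and 3 h of LPS the number of hotspots changed by -1578 and -1300 in the WT series and by -11862 in the littermate series, and rose by 9036 and 3977 in the KO series. The mean change was 11420 hotspots higher in KO than in controls. The covered length moved in the same directions, with a mean change 11.5 Mb higher in KO. In the WT series it changed by only -0.301 and -0.105 Mb. As deposited, each series of one kind moved one way and each of the other kind the opposite way. The WT replicate 1 list reached down to a Z-score of 8.29 at 0 h but only to 10.6 at 3 h. At rank 15659, the length of its 3 h list, the Z-score was 8.83 at 0 h and 10.6 at 3 h. Its fall thus came with a stricter cut, and at that cut the series did not fall. The cut was also stricter at 3 h in WT replicate 2 (9.29 to 9.37) and in the littermate (4.38 to 4.54). In both KO series it was looser (3.64 to 3.54 and 3.66 to 3.58). The direction of the change thus went with the cut in each series. Relative depth, if the density steps give it, fell in WT replicate 2 and the littermate and rose in the other series. The difference between KO and controls was not tested.

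That contrast sits on a wider pattern, the low Z-scores of the 6 control libraries at 0 h and 3 h. The 2 kinds of list, WT and the rest, each hold low and high libraries, so 4 libraries lie on the wrong side if the kind of list decided. WT libraries with 80 U and 100 U of DNase differed by a factor of at most 1.29 within a time. If the density steps give relative depth, dividing the Z-scores by depth still leaves the lowest of the other 9 libraries 1.80 times above the highest of the 6. Cultures or digestions handled on different days may have set the scores, and with no day in the labels the 2.20-fold gap between the lowest of the 9 and the highest of the 6 cannot be told apart from such a difference. A biological hypothesis, that KO cells at 0 h resemble LPS-treated controls, remains open too. Of the regions gained in controls at 8 h, 16.5% were in both KO 0 h lists, but this share reached 72.4% in the lists as deposited. Of regions gained in 2 control series, each KO 0 h library held 24.5% to 27.7%. The 0 h library of the control left out held 15.0% to 19.5%. Control 0 h libraries are among the 6 low ones, so this difference does not decide it.

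KO-gained regions numbered 3185, and 1 of the 27 splits that name 1 library per time as the littermate gave as many, the real one; the highest of the other splits gave 96. For the 357 KO-lost regions it was also 1 of 27, with 47 as the highest other. Other assignments of single libraries thus gave far fewer regions of both classes. The splits rename the littermate library at each time separately, although the littermate libraries form a single series. A chance difference of that series is therefore not excluded. Weak littermate libraries at 0 h and 3 h cannot be told apart from a difference between genotypes for the KO-gained regions. In both WT 8 h lists 4.71% of them were found, but absence from the similar littermate 8 h list is part of their definition, so this share decides nothing. Of 8687 regions in all KO and no littermate list at 0 h and 3 h alone, 48.4% were in the littermate 8 h list (Wilson 95% interval 47.3 to 49.4), between the bounds of 20% and 50% set for this test, and LPS could have opened these in controls; 39.7% were in no control 8 h list. If a single chromosomal segment carried along with the mutation held most KO-gained regions, they would lie on 1 chromosome. No chromosome held more than 8.10% of them. This share cannot show a short segment that holds few of the regions. A hypothesis that these regions are more accessible for lack of the targeted factor is consistent with these values but confounded with any other difference between the KO and control animals, cultures or libraries.

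For the LPS-gained regions at 8 h, 1 of 36 splits gave as many as the real 510, and the highest other gave 10. Lost regions at 8 h gave 1 of 36, with 204 against at most 6 in the smaller direction of other splits. At 3 h the 245 gained regions and the 187 lost regions each gave 1 of 36. Other splits gave at most 10 in their larger direction and at most 7 in their smaller direction. Weak control libraries at 0 h could make regions appear gained. KO lists would then hold regions gained in controls as often at 0 h as at 8 h, if KO libraries were equally strong at both times. At equal list length the share in both KO lists was 38.8 percentage points higher at 8 h. KO libraries were themselves weaker at 0 h, with Z-scores at equal rank of 25.9 and 25.1, against 35.6 and 40.01 at 8 h. The gap in the share therefore does not decide whether weak control libraries were the whole cause. The gap narrowed to 13.1 points with 50% of a region covered, and most such regions were in both KO 0 h lists as deposited, so the part of the gain that weak control libraries set cannot be told apart from the part that LPS set.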

How the results depend on the processing

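Ranking by the highest tag density, added after the data were seen, moved none of the counts below by more than 1.5 times, and under each alternative run gained regions outnumbered lost ones for LPS in all genotypes at 3 h and 8 h, LPS within WT at 8 h and within KO at 3 h and 8 h, KO against littermate over all 3 times and KO against all controls at 8 h. This did not hold for WT at 3 h, where lost regions were more numerous in 4 of 8 alternatives (1132 gained and 1598 lost as deposited; 2 of the 4 use a single series), nor for KO against littermate at 0 h and 8 h alone (at 3 h it held throughout): at 8 h 19320 were gained and 33943 lost as deposited and 4525 and 4740 with lists of 0.5 times the length, and at 0 h the main counts were 15983 and 16031. With a single list on 1 side or on both, equal length largely fixes the balance, so single series and single times at equal length neither support nor oppose an excess. Counts themselves moved with list length and with how regions were formed, and the causes were not tested beyond what each alternative does by construction. The depth of the libraries is unknown, and absence from a list does not show that a region was closed.

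In the lists as deposited, LPS-gained and lost regions numbered 1211 and 1 at 8 h, 30 and 3 at 3 h, and 21933 and 91 in WT at 8 h. KO-gained and KO-lost regions numbered 5876 and 135, KO-gained regions at 0 h 34833, and at 8 h against all controls 19678 and 621. Of control LPS-gained regions, 92.3% were in both KO 8 h lists and 72.4% in both KO 0 h lists, and the control left out held -10.2 percentage points relative to KO, a reversed difference.

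With lists of 0.5 times the equal length, fewer hotspots gave 187 and 83 LPS-gained and lost regions at 8 h, 116 and 90 at 3 h, 790 and 681 in WT at 8 h and 5469 gained in KO at 8 h. KO-gained regions numbered 1202, those at 0 h 5647, and those gained and lost at 8 h against all controls 3166 and 2204. The shares in KO were 62.1% and 24.4%, and the gap to the control left out was 16.7 points.

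With 50% of a union region covered, LPS-lost regions at 8 h numbered 21, gained and lost at 3 h 39 and 30, and gained in WT at 8 h 5150. KO-gained and KO-lost regions numbered 5086 and 152, KO-gained at 0 h 30892, and KO-lost at 8 h against all controls 2610. The shares in KO were 79.3% and 66.3%, and the gap was 6.72 points.

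Bins of 500 bp count a long region several times. LPS-gained and lost bins numbered 2408 and 436 at 8 h, 676 and 450 at 3 h, 17313 and 2719 in WT at 8 h and 37477 and 10204 in KO at 8 h. KO-gained and KO-lost bins numbered 14201 and 682, KO-gained at 0 h 79269, and at 8 h against all controls 33620 and 9047. The shares in KO were 74.5% and 52.3%, and the gap was 8.66 points.

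With a common Z-score minimum, also added later, LPS-gained and lost regions numbered 2536 and 2 at 8 h, 111 and 27 at 3 h, and 17490 and 81 in WT at 8 h. KO-gained and KO-lost regions numbered 5313 and 152, KO-gained at 0 h 28677, and at 8 h against all controls 11933 and 2103. The shares in KO were 83.2% and 58.3%, and the gap was 3.37 points.

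With the littermate as the only control, 50.5% of control LPS-gained regions were in both KO 8 h lists and 31.6% in both KO 0 h lists. With WT added to the controls, KO-gained and KO-lost regions numbered 330 and 42, as they did with the Fisher exact test per region, which at an adjusted 0.05 called just the regions that separate the 6 KO from the 9 control libraries; without adjustment it called 2298 and 1313.

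Leaving out 1 series at a time, LPS-gained and lost regions ranged from 613 to 795 and from 260 to 370 at 8 h, and from 309 to 429 and from 253 to 382 at 3 h. In WT at 8 h they ranged from 4129 to 5187 and from 3499 to 4062, and in KO at 8 h from 37003 to 38826 and from 35625 to 36295. A single series needs no agreement between replicates. Leaving out WT replicate 1 changed the list length too, within WT from 15659 to 20077 hotspots. The count of 288 lost at 3 h without the littermate also exceeded 1.5 times the full count. Shares of control LPS-gained regions ranged from 53.0% to 53.6% in both KO 8 h lists without 1 control series, and were 61.4% and 59.5% in the single KO 8 h list left without KO replicate 1 or 2. At 0 h they ranged from 20.3% to 22.4% in both KO lists, and were 20.6% and 22.0% in the single list. The excess of hotspots in KO over littermate was 42101 to 43606, with an exact permutation p of 0.25 for want of arrangements, and the similarity of same-time libraries exceeded that of other pairs by 0.0643 to 0.283, with p = 0.067 for the same reason. The mean change of hotspots from 0 h to 3 h ranged from -2691 to 2534, turning positive without the littermate. Covered length rose by 2.42 Mb (exact permutation p = 0.86, with the 8 h lists in the spread). The direction thus changed with the series and the measure, and neither direction is supported. The excess at 8 h over 0 h kept its direction and threshold in all 8 alternatives, with 80 U libraries alone among them (28541 hotspots, exact permutation p = 0.014).

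Replicate numbers are shared by WT and KO groups, but nothing in the labels makes them pairs: deviations of same-numbered libraries correlated by 0.0526 to 0.0675 in WT, where the number coincides with the DNase amount, and by -0.0010 to 0.0006 in KO. With the replicate number as a block, region counts stay the same by construction, 510 and 204 at 8 h, 245 and 187 at 3 h, 2150 in WT and 10783 in KO at 8 h, and 1377 and 7844 at 3 h. In the 16 splits that swap times within a number, no other split exceeded 10 gained regions at 8 h. The excess of 28924 hotspots at 8 h had an exact permutation p of 0.0069 with the block. The change of -345.4 at 3 h had an exact permutation p of 0.98, again with the 8 h lists in the spread. Of 146 alternatives for the counts and shares not given here, 58 stayed within 1.5 times or the interval and 88 moved, each count judged alone and not by which of gained and lost was larger. Alternatives for promoter shares, gene lists and motifs were not run.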

Other observations

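The tests in this part were chosen after the data were seen.

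KO-gained regions lay closer together than random regions of the same union. Of the 3185 regions, 16.0% had another within 20 kb, against a mean of 7.79% and a highest value of 9.83% in 1000 random draws (one-sided permutation p = 0.001, the smallest the draws can give). KO-lost regions did so too, with 8.96% against a mean of 0.899%, and so did each of the 5 classes tested, such as the LPS-gained regions at 8 h with 6.27% against a mean of 2.20% (permutation p = 0.001), so closeness was not particular to KO. Among 2577 windows of 1 Mb, 7 held an excess of KO-gained regions (exact hypergeometric test, adjusted p under 0.05). The strongest was chromosome X from 47000000 to 48000000, where 12 of 28 regions were KO-gained (exact hypergeometric test, adjusted p = 4.5e-08), and at 8 h 16 of its 18 regions were in both KO lists and in no control list (adjusted p = 3.8e-11). Of the hotspots of a list as deposited, 0.0181% to 0.0257% lay in this window in KO and 0% to 0.0134% in control lists. Chromosome 4 from 57000000 to 58000000 held 10 KO-gained regions of 59, with 0.0574% to 0.0711% of the list in KO and 0.00468% to 0.0437% in control lists, and chromosome 11 from 46000000 to 47000000 held 9 of 49, with 0.0502% to 0.0559% and 0.0128% to 0.0376%. The comparison at 8 h and these shares reuse KO and littermate lists that define KO-gained regions, so they are not separate support. The hypergeometric test treats regions as independent, although regions of each class lay close together.

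Chromosome X as a whole, that window included, was poor in KO-gained regions. It held 59 of 4004 regions (1.47%), against 3.14% over all chromosomes (Fisher exact test, adjusted p = 1.2e-09 over 105 tests), and in the comparison at 8 h with all controls 7.07% against 10.2% (adjusted p = 9.6e-05). KO-lost regions were more frequent there, 29 of 4004 or 0.724% against 0.353% (Fisher exact test, adjusted p = 0.0054), and 8.12% against 6.30% at 8 h (adjusted p = 0.014). Chromosome Y showed the same direction with few regions: 6 of 125 were KO-lost (4.80%, Fisher exact test, adjusted p = 0.00021) and 0 of 125 KO-gained (adjusted p = 0.16), and at 8 h 0 of 81 were KO-gained (adjusted p = 0.0054) and 11 of 81 KO-lost (adjusted p = 0.098). Each library listed hotspots on chromosome Y, 107 to 133 in KO, 114 to 132 in the littermate and 75 to 89 in the shorter WT lists as deposited. Chromosome 9 had the highest share of KO-gained regions, 3.99% (Fisher exact test, adjusted p = 0.0071). Regions are not independent replicates, so these p-values describe the regions of these libraries. The comparison at 8 h shares the KO and littermate 8 h lists with the comparison over all times, so it is not separate support.

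Some KO regions were strong and in no control list as deposited. By mean rank they were, after the chromosome 18 region already given, chromosome 11 from 57663776 to 57665345, chromosome 14 from 34900501 to 34902183, chromosome 9 from 58552771 to 58554847 and chromosome 2 from 91347537 to 91349324, with Z-scores in KO between 29.7 and 111.1. Regions in all 3 littermate lists and in no deposited KO list included chromosome 14 from 44495507 to 44496578 and chromosome 5 from 137632648 to 137633863, which were also in all 6 WT lists. These regions were chosen after their values were seen.

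Regions gained in KO at 8 h were looked up in the controls in turn. Of 2210 regions in both KO 8 h lists and in neither KO 0 h list (17237 hotspots per list), 39.9% were in all 3 control 8 h lists (Wilson 95% interval 37.8 to 41.9), 41.0% in none (39.0 to 43.1) and 5.29% in all 3 control 0 h lists.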
